A study of Mus musculus with 6 samples.

How the data were processed

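RNA was measured in glomeruli isolated from mice, in 3 Control and 3 DKD libraries. Per the labels' protocols, polyadenylated RNA was made into dUTP stranded libraries and sequenced in paired reads of 150 bases. Per the submitters' processing notes the tools were fastp, HISAT2, StringTie and edgeR with the mouse build GRCm39. The versions, the annotation release and whether counting used the strand are not given in the sources used here. The authors deposited raw counts per Ensembl gene, without normalization, for 55401 genes, of which 30837 were above 0 in at least 1 library. Whole numbers were found throughout. Values of 4 occurred 6267 times and values of 8 occurred 2929 times, against 3129 for 3, 1993 for 5, 1784 for 7 and 1305 for 9, so the deposited counts may be coverage estimates converted to whole reads. The totals ran from 71154026 to 83576494 counts per library.

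Symbols and gene models came from a mouse annotation on the preceding build, GRCm38, so positions are not printed. Of the Ensembl identifiers 55141 matched and 260 did not, and the latter held a mean of 0.00808% of the Control counts. Transcript length, GC content, shared exons and shared 31-base words were computed from the same annotation.

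Genes were kept by filterByExpr with the group (minimum count 10), which left 19717. Libraries were scaled with TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Log2 fold changes are DKD over Control, and each ± beside one is a standard error. Gene lists were tested with camera of limma 3.58.1 on log CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 27 lists, and again with an estimated correlation and with fry. Shares of counts were compared with an exact permutation test. The biological coefficient of variation was 33.2%. No library duplicated another within its group, with log CPM correlations between 0.954 and 0.980.

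The tests, the 27 lists and the rule for naming genes were set before the data were examined. The rule takes Setdb2 and Smad3, and the methyltransferases past the threshold. It takes the 10 largest rises and falls among genes past the threshold with at least 5 CPM in the higher group and no overlap between groups, leaving out predicted and clone-named models. It also takes up to 4 members past the threshold per list, or otherwise the 2 with the smallest p, and up to 3 of the most abundant members of a cell type list as levels. It took 72 genes, of which 38 passed, and some items it took are not reported here.

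Alternatives chosen before the data were examined were RLE factors, upper quartile factors, library totals, a filter of at least 1 CPM in at least 3 libraries, no filter, DESeq2 1.42.0, limma-voom, robust dispersion, the replicate number as a block, a proximal tubule score as a covariate, an estimated correlation, other thresholds, and each library left out in turn. Chosen after the data were seen were leaving out mitochondrial genes with their nuclear copies, and removing a smooth trend on transcript length or on GC content (5 degrees of freedom) in each library. The procedure was tested on simulated data with 3 libraries per group. It recovered 35 of 100 genes changed by a log2 fold of 1 and 80 of 100 changed by 2, and 7 of 125 genes called were unchanged ones. No library was left out of the reported values.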

Results

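Glomeruli, the filtering units of the kidney, were isolated from mice, and their polyadenylated RNA was sequenced. The labels name 2 groups, Control and DKD, with 3 libraries each, and the title of the series spells out DKD as diabetic kidney disease. How the disease was induced is not stated in the labels. Markers of the proximal tubule, outside the glomerulus, held 6.07% ± 1.55 (mean ± SD) of the Control counts and 4.31% ± 0.557 of the DKD counts. The libraries thus held tubule RNA too, and the changes below cannot be assigned to glomerular cells alone. The deposited table held read counts for 55401 Ensembl genes, with totals of 74239752, 72451052 and 83576494 counts in Control replicates 1 to 3 and 73435328, 71154026 and 75328417 counts in DKD replicates 1 to 3. The labels number the samples without saying that each came from its own animal, so the p-values measure the spread between these libraries. Levels below are in CPM, counts scaled to a common library size with TMM factors, as mean ± SD with n = 3 per group. Control replicate 3 stood apart from its group. On the first principal component of log CPM (39.8% of the variance) it lay at −101, against −18.0 and −15.0 for Control replicates 1 and 2, and on the next (26.5%) at −46.8 against 59.4 and 60.0. Its log CPM correlated at 0.956 and 0.954 with those libraries across genes, which correlated at 0.980 with each other.

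The series asks how transcripts of histone methyltransferases, the enzymes that place methyl groups on histones, differ in DKD. No methyltransferase passed the edgeR test, whereas DESeq2 called 6, including Setdb2. Setdb2, a SET-domain lysine methyltransferase (ENSMUSG00000071350), was measured at 9.73 ± 0.642 CPM in Control and 6.12 ± 1.28 CPM in DKD. All 3 DKD libraries lay below all 3 Control libraries, and the log2 fold change was −0.67 ± 0.20 (SE), with an adjusted p of 0.124 by edgeR. Smad3, which encodes a transcription factor of TGF-beta signalling (ENSMUSG00000032402), was measured at 43.1 ± 4.16 CPM in Control and 38.4 ± 5.81 CPM in DKD. The Smad3 values of the groups overlapped, with a log2 fold change of −0.17 ± 0.14 and an adjusted p of 0.535.

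Of the 50 listed methyltransferases, 48 were measured, and edgeR called 0 of them, both over all genes tested and adjusted over the list alone. The smallest adjusted p was 0.0957 over all genes and 0.124 over the list. At an unadjusted p under 0.05 there were 10 (2 higher and 8 lower in DKD), where 2.4 are expected by chance. That was 20.8% of them, against 22.6% of all genes tested (4458 of 19717). The groups did not overlap for 16 of the 48 (33.3%), against 30.7% of all genes and a chance share of 10%. Kmt5a, which methylates histone H4, had a log2 fold change of 0.61 ± 0.16 (77.5 ± 12.1 against 118 ± 17.0 CPM). Carm1, an arginine methyltransferase, had 0.34 ± 0.10. Ash1l had −0.45 ± 0.13 and Prmt9 −0.22 ± 0.13. The 40 lysine methyltransferases had a median log2 fold change of −0.097 and a camera adjusted p of 0.0641 (adjusted p = 0.739 with an estimated correlation), and 25 of them were lower in DKD. Leaving out 1 library at a time, that p ran from 0.0368 without DKD replicate 2 (median −0.18) to 0.175 without DKD replicate 3 (median −0.061). It was 0.0356 with limma-voom, 0.0460 with robust dispersion and 0.0475 with a trend on GC content removed. Among the 8 arginine methyltransferases 4 were higher and 4 lower, with a camera adjusted p of 0.931. Their median was −0.024 while their mean was 0.005. Of single methyltransferases, limma-voom and edgeR with robust dispersion also called 0, whereas DESeq2 called 6. Those 6 were Kmt5a and Carm1, higher in DKD, and Ash1l, Ezh1, Nsd1 and Setdb2, lower in DKD (Ezh1 and Nsd1 are named here after their values were seen). Over all genes DESeq2 called 2483 of 18167, where edgeR called 228 of 19717, so its calls were not particular to methyltransferases. The adjusted p of Setdb2 was 0.0249 with DESeq2 and ranged from 0.0249 to 0.408 over the alternatives. Across 14764 genes, which are not independent replicates, the log2 fold change had a Spearman correlation of −0.331 with log2 transcript length. With the trend on transcript length removed the lysine list had a median of 0.027 (camera adjusted p 0.891) and 5 methyltransferases had an unadjusted p under 0.05.

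**Figure D1:**
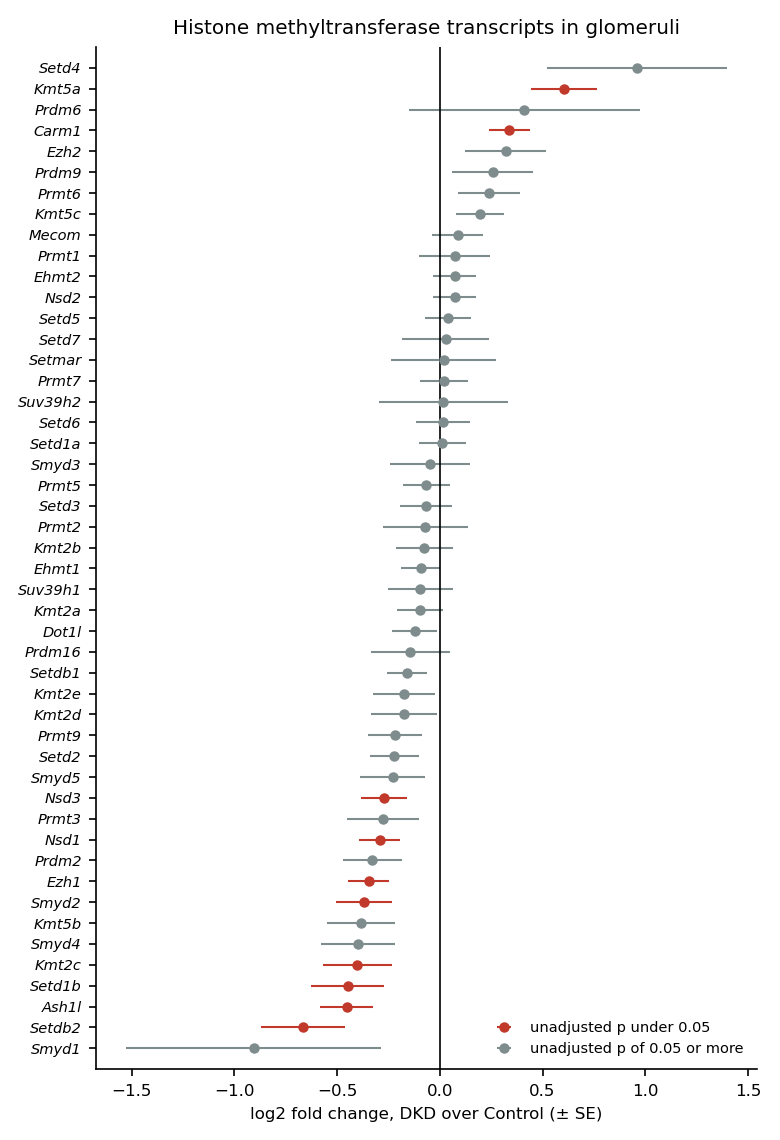
Log2 fold change (DKD over Control, horizontal axis) of the 48 measured histone methyltransferases, with bars of 1 standard error from edgeR, n = 3 libraries per group. Red marks the 10 with an unadjusted p under 0.05 by edgeR, and none of the 48 had an edgeR adjusted p below 0.0957.

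The opposing enzymes and the SMAD pathway were listed beside the methyltransferases. Histone lysine demethylases were lower in DKD as a list, with 18 of 21 members lower and a median of −0.17. The camera adjusted p was 0.00351 (adjusted p = 0.647 with an estimated correlation). By edgeR no demethylase passed the threshold over all genes or adjusted over the list alone, and 7 had an unadjusted p under 0.05. Kdm6a was measured at −0.56 ± 0.15 and Kdm2b at −0.50 ± 0.14. Each passed the threshold in 1 alternative setting and did not in 18. With the length trend removed, the demethylase list had a median of −0.072 and a camera adjusted p of 0.296. In the list of TGF-beta, BMP and SMAD genes, 1 of 45 members passed over all genes. This was Grem1, which encodes a secreted antagonist of bone morphogenetic proteins, and it rose from 0.689 ± 0.629 to 28.4 ± 7.01 CPM (log2 fold change 5.36 ± 0.68, adjusted p 0.0263). Adjusted over the list alone, 2 members rose and 4 fell. The list median was −0.19, with 32 of 45 members lower and a camera adjusted p of 0.0677 (adjusted p = 0.781 with an estimated correlation). That p was 0.00589 without Control replicate 3 and 0.00957 without DKD replicate 3, but 0.181, 0.198 and 0.421 without Control replicate 1, Control replicate 2 and DKD replicate 1, where the median was −0.11, −0.14 and −0.092. It was 0.0498 with limma-voom and 0.0443 with the GC trend removed. With a score of proximal tubule markers as a covariate it was 8.83e-06, with a median of −0.44, and with the length trend removed it was 0.492. That score, a mean log2 CPM, ran from 9.637 to 10.37 in Control and from 8.995 to 9.479 in DKD. The groups did not overlap on it, so fits with this score, here and below, cannot tell tubule content and group apart.

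Over the whole transcriptome 228 of 19717 genes changed, 143 of them higher and 85 lower in DKD. With an absolute log2 fold change of at least 1 there were 168, split into 107 higher and 61 lower. The 10 largest rises included Ighg1 (0.488 ± 0.227 to 22.9 ± 4.38 CPM, log2 fold change 5.54 ± 0.40) and Ighg3 (4.64 ± 0.50), which encode constant regions of immunoglobulin heavy chains. They also included Grem1, the bilirubin-conjugating enzyme Ugt1a1 (4.70 ± 0.68), the protease inhibitor Slpi (3.94 ± 0.67) and the cell division genes Cdkn3 (3.68 ± 0.60), Cdca3 (2.98 ± 0.44) and Birc5 (2.85 ± 0.41). The mitochondrial tRNA mt-Ti (3.15 ± 0.47) was also among them. The largest fall was in Ces1g, a carboxylesterase, from 65.8 ± 17.6 to 2.37 ± 1.09 CPM (−4.80 ± 0.39). It was followed by Cyp4b1-ps2 (−3.67 ± 0.37), Cyp2d12 (−3.32 ± 0.54), Clec2h (−3.04 ± 0.42), Cpne4 (−2.87 ± 0.37), Fam151a (−2.76 ± 0.32), Slc34a3 (−2.74 ± 0.33), Wfdc16 (−2.62 ± 0.37), Slc5a12 (−2.56 ± 0.25) and Ano3 (−2.48 ± 0.23). Slc34a3 is a sodium-dependent phosphate transporter and Slc5a12 a sodium-coupled lactate transporter of the tubule. Adjusted p-values of the 10 largest rises and 10 largest falls lay between 0.0104 for Ighg1 and 0.0491 for Slpi. Reads of some named genes can be shared with other genes. Other Ugt1a genes cover 58.9% of the exonic bases of Ugt1a1, and transcripts of other genes hold 46.2% of the 31-base words of Cyp4b1-ps2. Fam151a lies over Acot11 on the opposite strand along 65.7% of its exonic bases, and whether strand was used in counting is not stated. Groups did not overlap for 6049 genes (30.7%, where chance gives 10%). With library totals as the only scaling, the median of all genes shifted by −0.13 and 275 genes passed, 101 higher and 174 lower. The count depended on single libraries: 1 gene passed without Control replicate 1 (Gm15441), 13 without Control replicate 2, 386 without Control replicate 3, 4 without DKD replicate 1 (Agt, Ces1g, Gm15441 and Sucnr1), 298 without DKD replicate 2 and 10 without DKD replicate 3 (Gm15441 and Sucnr1 are named after their values were seen). Of the 38 genes past the threshold that the naming rule took, these fits kept 0, 7, 34, 2, 27 and 4 in the same order, and none changed direction.

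**Figure D2:**
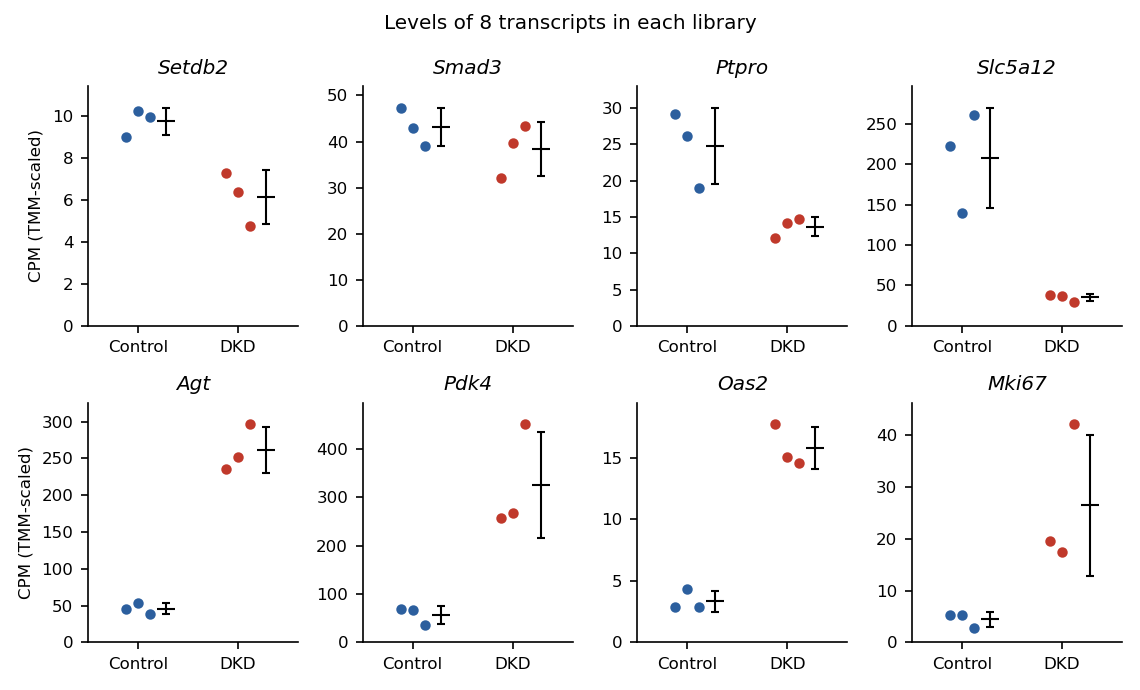
TMM-scaled CPM (vertical axes, starting at 0) of 8 transcripts in each of the 3 Control (blue) and 3 DKD (red) libraries, with mean ± SD in black. Agt, Pdk4, Oas2 and Mki67 were higher and Slc5a12 was lower in every DKD library. Setdb2 and Ptpro did not pass the adjusted threshold in the reported edgeR fit, and the Smad3 values overlapped.

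Markers of the proximal tubule, the segment that follows the glomerulus, took the largest share of counts among the cell type lists. The 34 proximal tubule markers held 6.07% ± 1.55 of the counts in Control and 4.31% ± 0.557 in DKD, against 0.319% ± 0.0527 and 0.235% ± 0.0196 for the podocyte markers. In an exact permutation test each of these comparisons gave p = 0.1 (two-sided), the smallest that 3 against 3 allows. The endothelial share also gave an exact permutation p = 0.1 (0.149% ± 0.0112 and 0.104% ± 0.0273), and the mesangial share an exact permutation p = 0.8. Median CPM of the members gave an exact permutation p = 0.2 for proximal tubule and 0.3 for podocyte markers. Their mean log2 CPM gave an exact permutation p = 0.1 and 0.2 in that order. Abundant proximal tubule members included Kap at 12954 ± 7148 and Slc34a1 at 4496 ± 1858 CPM in Control. As a list the proximal tubule markers were lower in DKD, with 29 of 34 lower, a median of −0.64 and a camera adjusted p of 4.83e-06 (adjusted p = 0.647 with an estimated correlation). Over all genes 3 fell, namely Slc5a12, the glucose transporter Slc5a2 (−1.82 ± 0.30) and the amino acid transporter Slc7a8 (−1.12 ± 0.16). Adjusted over the list alone, 14 fell and 2 rose, the latter being Pck1, an enzyme of gluconeogenesis, and Slc13a1 (named after their values were seen). Control replicate 3 had the highest share of proximal tubule markers, 7.84%, and without it the median was −0.33 with a camera adjusted p of 0.00491. With a score built from these markers as a covariate their median was 0.052.

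Podocyte markers, from the epithelial cells that cover the glomerular capillaries, were also lower in DKD as a list. Of 40 members 32 were lower, with a median of −0.36 and a camera adjusted p of 0.000237 (adjusted p = 0.647 with an estimated correlation). Over all genes 0 passed with edgeR, 15 had an unadjusted p under 0.05, and 8 fell when adjusted over the list alone. Ptpro, a podocyte phosphatase, was measured at 24.8 ± 5.24 and 13.7 ± 1.36 CPM (−0.86 ± 0.18, adjusted p 0.0637) and Robo2 at 10.5 ± 2.82 and 4.44 ± 1.5 CPM (−1.24 ± 0.31, adjusted p 0.0851). Ptpro passed the threshold in 3 alternative settings and Robo2 in 2, and they did not in 16 and 17. The podocyte median was −0.24 without Control replicate 1 and −0.64 with the tubule score as covariate. The most abundant members were Actn4 at 345 ± 10.5, Itgb1 at 271 ± 26.5 and Col4a3 at 264 ± 15.4 CPM in Control.

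Other cell type lists did not pass the camera test. The 24 mesangial and smooth muscle markers had a median of −0.21 and a camera adjusted p of 0.145, and 1 member, the angiotensin receptor Agtr1a, fell over all genes and over the list alone (−1.07 ± 0.16, adjusted p 0.0360). The 29 endothelial markers had a median of −0.14 and a camera adjusted p of 0.1. By edgeR 0 of them passed over all genes, 5 had an unadjusted p under 0.05, and 2 fell adjusted over the list alone. Ehd3 was measured at −0.76 ± 0.14 and Kdr, a receptor for vascular endothelial growth factor, at −1.06 ± 0.21. The mesangial list had a camera adjusted p of 0.000152 and a median of −0.43 without Control replicate 3, but medians of −0.088, −0.093 and −0.11 without Control replicate 1, Control replicate 2 and DKD replicate 1 (p 0.598, 0.491 and 0.353). The endothelial list had a camera adjusted p of 0.00641 without Control replicate 3, but medians of −0.013 and 0.036 without Control replicate 1 and DKD replicate 1 (p 0.404 and 0.589). It had 0.0104 without DKD replicate 3 and 0.0406 with the GC trend removed. With the tubule score as covariate the mesangial median was −0.96 (camera adjusted p 1.72e-07) and the endothelial median −0.74 (6.91e-06). The 13 parietal epithelial markers had a median of 0.34 (camera adjusted p 0.0802), with Krt8 at 0.84 ± 0.20 and Cd9 at 0.66 ± 0.23, and the camera p was 0.0271 without Control replicate 1, 0.0121 without Control replicate 2, 0.999 without Control replicate 3 (median 0.18), 0.0463 with limma-voom and 0.0348 with the length trend removed. With the tubule score as covariate the parietal median was −0.77 (camera adjusted p 0.0320). The 27 markers of the loop, distal tubule and collecting duct had a median of −0.21 (camera adjusted p 0.173), with 3 members lower when adjusted over the list alone, Slc26a4 at −1.36 ± 0.24 and Slc4a1 at −0.94 ± 0.19, and the camera p was 0.0465 without DKD replicate 1 (median −0.14) and 0.722 without Control replicate 3 (median −0.20), with medians of −0.077 without DKD replicate 2 and −0.11 without Control replicate 1. The 32 leukocyte markers had a median of 0.32 (camera adjusted p 0.0901), with Cd79a at 2.37 ± 0.59 and Cd14 at 2.07 ± 0.56. The leukocyte camera p was 0.0314, 0.0112 and 7.77e-05 without Control replicate 1, Control replicate 2 and DKD replicate 1, and without Control replicate 3, DKD replicate 2 and DKD replicate 3 the median was 0.039, 0.17 and 0.11 (p 0.998, 0.414 and 0.550). That p was 0.0302 with library totals and 0.0460 with robust dispersion, and with the tubule score as covariate the leukocyte median was −0.69 (camera adjusted p 0.000539). Leukocyte markers held 0.0481% of the counts in Control replicate 3, 0.130% and 0.163% in Control replicates 1 and 2, and between 0.0677% and 0.154% in DKD. The 8 erythrocyte transcripts had a median of 0.53 (camera adjusted p 0.736), with Bpgm at −0.29 ± 0.12 and Slc25a37 at 0.14 ± 0.12.

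As lists, fatty acid oxidation genes were higher in DKD and lipid and sterol synthesis genes were lower, though members went both ways. Of 32 oxidation genes 5 rose and 0 fell over all genes (16 and 1 adjusted over the list alone), with a median of 0.37 and a camera adjusted p of 0.000918 (adjusted p = 0.647 with an estimated correlation). They included Pdk4, a kinase that inhibits pyruvate dehydrogenase (57.3 ± 18.4 to 324 ± 109 CPM, 2.50 ± 0.33), the lipase inhibitor Angptl4 (1.28 ± 0.15), the carnitine palmitoyltransferase Cpt1b (1.19 ± 0.15) and the carnitine carrier Slc25a20 (0.94 ± 0.12). An overlapping gene model covers 81.4% of the exonic bases of Cpt1b. The oxidation median was 0.22 with the length trend removed, 0.24 with library totals and 0.63 with the tubule score as covariate. Of 27 lipid synthesis genes 2 fell over all genes (13 fell and 1 rose adjusted over the list alone), with a median of −0.54 and a camera adjusted p of 2.4e-05 (adjusted p = 0.647 with an estimated correlation). They included the isoprenoid enzyme Idi1, which fell from 59.8 ± 25.5 to 13.5 ± 3.32 CPM (−2.14 ± 0.33). The glycolysis and glucose uptake list covered 23 rows, since Aldoa has 2, with a median of 0.38 and a camera adjusted p of 0.00246 (adjusted p = 0.581 with an estimated correlation). Its single member past the threshold was the phosphofructokinase Pfkp (1.5 ± 0.19, edgeR adjusted p 0.0263), and 4 rose adjusted over the list alone. With the tubule score as covariate the glycolysis median was 0.22 and its camera adjusted p 0.110.

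Transcripts of the respiratory chain were higher in DKD. Of 68 nuclear-encoded subunits of oxidative phosphorylation 65 were higher, with a median of 0.54 and a camera adjusted p of 2.4e-14 (adjusted p = 0.647 with an estimated correlation). Over all genes 1 rose, the complex I subunit Ndufb8 (137 ± 11 to 244 ± 25.2 CPM, 0.84 ± 0.13), and 47 rose adjusted over the list alone. All 13 mitochondrially encoded protein genes were higher, with a median of 0.80 and a camera adjusted p of 2.78e-06 (adjusted p = 0.647 with an estimated correlation). Of these 0 passed over all genes with edgeR, 8 had an unadjusted p under 0.05 and 7 rose adjusted over the list alone. Among them mt-Nd6 was measured at 1.38 ± 0.29 and mt-Nd2 at 1.00 ± 0.30. Mitochondrially encoded genes held 11.5% ± 0.797 of all counts in Control and 17.5% ± 1.90 in DKD (exact permutation p = 0.1, two-sided). Nuclear copies of these genes held a further 2.76% and 4.13%, and the copy Gm28437, named after its values were seen, lay within 1.4% of the count of mt-Co3 in every library. With the trend on transcript length removed the nuclear list had a median of 0.26 and the mitochondrial list 0.41. Genes of oxidative stress and NRF2 targets had a median of 0.39 over 30 members and a camera adjusted p of 0.00776 (adjusted p = 0.647 with an estimated correlation). Among them Gclc, of glutathione synthesis, rose from 252 ± 29.3 to 582 ± 77.6 CPM (1.21 ± 0.17), and 5 rose and 2 fell adjusted over the list alone. This list had a camera adjusted p of 0.103 with the tubule score as covariate.

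Interferon-stimulated and cell cycle genes were higher in DKD as lists. Of 28 interferon-stimulated genes 25 were higher, with a median of 0.74 and a camera adjusted p of 1.22e-06 (adjusted p = 0.647 with an estimated correlation). Over all genes 3 rose, namely Oas2 (3.33 ± 0.848 to 15.8 ± 1.70 CPM, 2.24 ± 0.22), Ifi27 (1.61 ± 0.24) and Oas1a (1.64 ± 0.27), and 9 rose adjusted over the list alone. Transcripts of other genes hold 68.8% of the 31-base words of Oas1a. Without Control replicate 3 the interferon median was 0.45, and with the tubule score as covariate it was 0.045 with a camera adjusted p of 0.681. Of 25 cell cycle genes 23 were higher, with a median of 2.46 and a camera adjusted p of 3.88e-09 (adjusted p = 0.647 with an estimated correlation). Birc5, Mki67 (4.46 ± 1.44 to 26.5 ± 13.6 CPM, 2.57 ± 0.41) and Cenpf (2.71 ± 0.46) rose over all genes, and 19 rose and 1 fell adjusted over the list alone. The cell cycle median was 1.64 without DKD replicate 3 and 1.12 with the tubule score as covariate (camera adjusted p 0.000162). The 32 inflammatory mediators had a median of 0.52 and a camera adjusted p of 0.00109 (adjusted p = 0.739 with an estimated correlation), with 0 past the threshold over all genes by edgeR, 10 at an unadjusted p under 0.05 and 6 higher adjusted over the list alone. Complement C3 was measured at 3.40 ± 0.73 and Cxcl10 at 1.69 ± 0.40. Without Control replicate 3 the inflammatory list had a median of 0.20 and a camera adjusted p of 0.112, without Control replicate 1 its median was 0.90, and with the tubule score as covariate it was −0.29 with a camera adjusted p of 0.113. The 13 genes of senescence and cell-cycle arrest had a median of 0.42 and a camera adjusted p of 0.0493 (adjusted p = 0.647 with an estimated correlation), which became 0.140 without DKD replicate 2, 0.0636 without DKD replicate 3, 0.0536 with upper quartile factors, 0.129 with the CPM filter, 0.0736 with DESeq2 and 0.681 with the tubule score as covariate. Without Control replicate 3 the senescence median was 0.23. Igfbp3 was measured at −1.81 ± 0.37 and Cdkn2c at 1.16 ± 0.25, and 4 members rose and 1 fell adjusted over the list alone.

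Among 11 genes of the renin-angiotensin system Agt, which encodes angiotensinogen, rose from 45.9 ± 7.39 to 261 ± 31.4 CPM (2.51 ± 0.17, adjusted p 0.0103), while the receptor Agtr1a, also in the mesangial list, fell. The list had a median of −0.42 and a camera adjusted p of 0.497, and 2 members rose and 4 fell adjusted over the list alone. That median was −0.71 without DKD replicate 2, −0.23 without Control replicate 3 and −0.26 without DKD replicate 3. Extracellular matrix and fibrosis genes were split evenly, with 22 higher and 22 lower and a camera adjusted p of 0.701. Fbln5 was measured at −1.27 ± 0.32 and Col6a3 at −0.78 ± 0.23. Without Control replicate 3 the matrix list had a median of −0.26 and a camera adjusted p of 0.0107, and without Control replicate 1 its median was 0.23. Its median was −0.87 with the tubule score as covariate (camera adjusted p 6.27e-08), though that score did not overlap between the groups. Of 15 mesenchymal transition markers 13 were lower (median −0.26, camera adjusted p 0.133), with Ctnnb1 at −0.45 ± 0.15 and S100a4 at 1.05 ± 0.40, and the camera p was 0.0240 without Control replicate 3, 0.0423 without DKD replicate 3, 0.440 without Control replicate 2 (median −0.044), 0.589 without DKD replicate 1 (median 0.032) and 7.86e-05 with the tubule score as covariate (median −0.83). Another gene model covers 51.7% of the exonic bases of S100a4. The 23 genes of the unfolded protein response had a median of −0.13, a mean of 0.049 and a camera adjusted p of 0.701, with Ern1 at −0.61 ± 0.15 and Ddit3 at 0.65 ± 0.17. The 27 immediate-early and heat-shock genes had a median of 0.28 and a camera adjusted p of 0.0643, with Myc at 1.47 ± 0.30, Jund at 0.79 ± 0.20 and 1 member higher adjusted over the list alone, and the camera p was 9.32e-05 without Control replicate 2, 0.0113 without DKD replicate 1, 0.893 without Control replicate 3, 0.173 without DKD replicate 2 and 0.0846 without DKD replicate 3. In the last 3 the median was 0.15. That p was 0.0320 with library totals, 0.0348 without a filter and 0.0365 with limma-voom. With the tubule score as covariate the immediate-early median was −0.40 and that of the unfolded protein response 0.305 (camera adjusted p 0.0496 for each). In all, 13 of the 27 lists passed camera with its preset correlation, 9 higher and 4 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.581 and 1 list had an unadjusted p under 0.05. By fry, which asks whether the genes of a list move on balance in the same direction, 0 of 27 passed (smallest adjusted p 0.0601), and 16 passed its test for change in either direction. That last test does not compare a list with other genes, and 22.6% of all genes tested had an unadjusted p under 0.05 by edgeR. The 16 are therefore not particular to these lists.

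**Figure D3:**
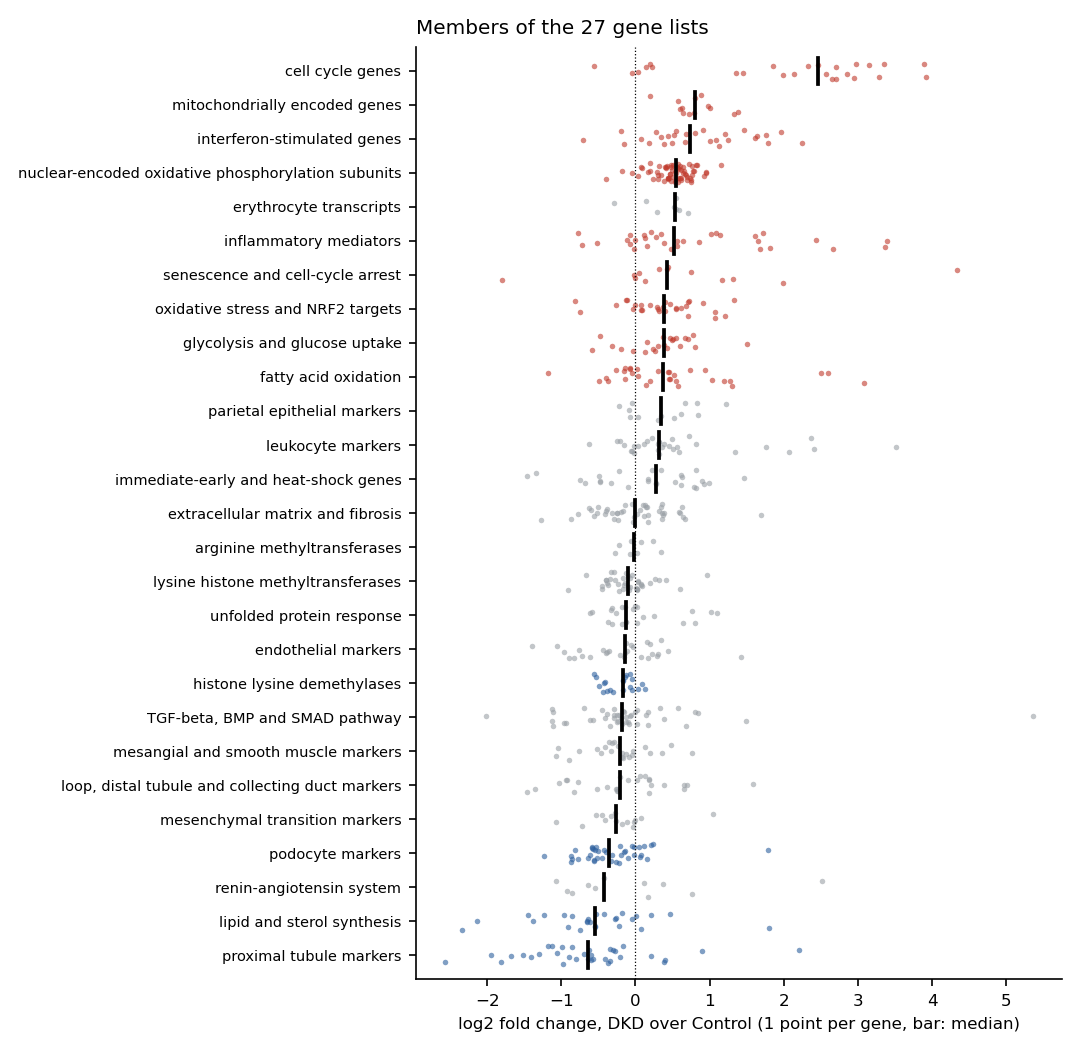
Log2 fold change (DKD over Control, horizontal axis) of each measured member of the 27 gene lists, with a black bar at the median. Red and blue lists passed camera with its preset correlation, higher and lower in DKD, with medians from −0.64 for proximal tubule markers to 2.46 for cell cycle genes, and grey lists did not pass.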

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

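Removing the length or GC trend and leaving out mitochondrial genes were chosen after the results were seen; the other alternatives were not. Of the 72 genes taken by the naming rule none changed direction under any alternative run; genes named after their values were seen were not followed through the alternatives. The count of 228 changed genes was 56 without a filter, 516 with the CPM filter, 2483 with DESeq2, 86 with the proximal tubule score as covariate, and 1363 at an unadjusted p under 0.05 with an absolute log2 fold change of at least 1. The number of genes tested is part of the construction of the CPM filter (15046) and of the fit without a filter (30837), against 19717. The count at an unadjusted p leaves out the adjustment by construction. For DESeq2 and the tubule score the cause was not tested. With the replicate block the count of changed genes was 0 by edgeR, and 9 methyltransferases then had an unadjusted p under 0.05. The lysine methyltransferase and TGF-beta lists then gained a call (camera adjusted p 0.0437 for each). Between libraries of the same number, deviations from the group means correlated at −0.183, 0.066 and −0.224, and 0 of 3 correlated best with its own number. These values gave no sign that the numbers pair the samples, though 3 correlations cannot exclude it. Leaving out a library gave between 1 and 386 genes, with fewer samples in each fit. DESeq2 called 6 methyltransferases where edgeR called 0. With an estimated correlation 0 lists passed.

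Outside the fits that leave out a library, list results were the same in 324 cases, weaker in 20, stronger in 20 and opposite in sign in 13. With the tubule score as covariate, medians were −0.773 for parietal, 0.052 for proximal tubule, −0.692 for leukocyte, −0.287 for inflammatory, 0.305 for unfolded protein response, −0.399 for immediate-early, −0.008 for senescence and 0.174 for renin-angiotensin genes. The matrix median then was −0.866, mesangial −0.958, mesenchymal −0.832, endothelial −0.738 and TGF-beta −0.441, each gaining a call, while interferon (0.045), glycolysis (0.224) and NRF2 (0.307) genes lost theirs and the cell cycle median was 1.121. That score is built from the proximal tubule list itself, and for the other lists the cause was not tested. The score was higher in every Control library than in any DKD library. These fits therefore do not show what would hold at equal tubule content. The matrix median, −0.001, was 0.012 with upper quartile factors, 0.041 with limma-voom, 0.046 with the replicate block and 0.105 with the length trend removed, and the lysine methyltransferase median was 0.027 with the latter. Leaving out a library gave matrix medians from −0.257 to 0.226, arginine methyltransferase −0.055 to 0.088, mesenchymal −0.424 to 0.032, endothelial −0.341 to 0.036, erythrocyte −0.33 to 0.912 and unfolded protein response −0.23 to 0.118. The mitochondrially encoded list has no value where its genes were left out. At this depth and n, 35 of 100 simulated changes of a log2 fold of 1 were recovered, so many changes of that size can be missed.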

Other observations

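The gene lists of the next 2 paragraphs, the tests on the share of glomeruli and of proximal tubule, and the removal of length and GC trends were chosen after the results were seen. Set tests of these lists were adjusted over the 7 lists added then, not over the 27. Standard errors of list medians and the bootstrap interval below came from resampling list members. Members of a list are not independent, so these errors do not measure the spread between libraries.

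Targets of PPAR-alpha, a nuclear receptor for fatty acids, were higher in DKD as a list, with 11 of 35 past the threshold, 20 higher and 1 lower adjusted over the list alone and a median of 0.94. The edgeR calls included Vnn1 (111 ± 5.43 to 312 ± 36.5 CPM, log2 fold change 1.49 ± 0.14), the mitochondrial carrier Ucp2 (1.70 ± 0.23), the thioesterase Acot2 (1.68 ± 0.19) and Cyp4a31 (0.96 ± 0.14), beside the oxidation genes Pdk4, Angptl4, Cpt1b and Slc25a20. Camera gave an adjusted p of 4.18e-10 (adjusted p = 0.0279 with an estimated correlation). Among 13 apolipoproteins Apoa4 (1.59 ± 0.14), Apoc3 (2.29 ± 0.34) and Apoa2 (1.51 ± 0.25) rose and Apom fell from 66.0 ± 7.43 to 19.4 ± 2.13 CPM (−1.77 ± 0.14). Gene models on the opposite strand cover 69.8% of the exonic bases of Apoa4. Of 19 circadian clock genes 1 rose over all genes, Cry1 (1.53 ± 0.21), and the list had a median of −0.33 (camera adjusted p 0.407). By edgeR 8 had an unadjusted p under 0.05, and 3 rose and 3 fell adjusted over the list alone. Control replicate 3 stood apart in some of them, such as Per2 at 57.7 CPM against 16.3 and 26.8 in Control replicates 1 and 2, but not in Cry1 (3.11 against 2.87 and 3.82).

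All 135 measured immunoglobulin segments were higher in DKD, with 5 past the edgeR threshold, 41 adjusted over the list alone and a median of 2.23 (adjusted p = 0.130 with an estimated correlation). The filter could keep a segment through its DKD counts alone, so the count of higher segments was partly fixed by the filter. Ighv6-6, for example, had 0 counts in every Control library. Some rises rested mainly on a single library, such as Igkv3-2 at 0.792, 0.637 and 24.6 CPM in DKD replicates 1 to 3 (both named after their values were seen). The smallest adjusted p of all genes, 0.000636, belonged to Gm15441, which rose from 2.53 ± 0.273 to 33.1 ± 3.48 CPM (3.71 ± 0.15). Its exons lie over the opposite strand of Txnip along 36.2% of their bases, and Txnip had a log2 fold change of 0.38 ± 0.17. Both mitochondrial rRNAs rose, mt-Rnr2 from 473 ± 82.7 to 3093 ± 1196 CPM (2.71 ± 0.34) and mt-Rnr1 from 420 ± 55.7 to 1908 ± 577 CPM (2.18 ± 0.27).

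Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many genes as the real split, which was the real split itself. It gave 228 genes, and the highest of the others gave 0. With 10 splits the share is never under 0.1, too few for a share under 0.05.

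Transcripts of nuclear-encoded oxidative phosphorylation subunits, of mitochondrially encoded protein genes and of mitochondrial rRNA were each higher in DKD. As lists they did not pass camera with an estimated correlation. The adjusted p was then 0.647 for nuclear-encoded subunits and for mitochondrially encoded protein genes, over the 27 lists. It was 0.130 for the mitochondrial rRNAs, over the 7 added lists. With the GC trend removed, the median log2 fold change of the nuclear subunits was 0.518 against 0.54, which argues against that trend. With the length trend removed it was 0.261 (standard error over members 0.015, camera adjusted p 1.01e-08), just under 50% of 0.54. That bound was written before this test was run, though after the shift itself was seen. A median under the bound was the outcome written for length as the cause. The written test thus came out for length, though by less than that standard error, and a large part of the shift may go with it. What remained was past the threshold at the preset correlation, so length need not be the whole cause (without this removal the list had adjusted p = 0.647 with an estimated correlation). More RNA without a poly(A) tail in the DKD libraries cannot be told apart from a change in the cells. The 45 such RNAs measured had a median of 0.147, below the bound written before that test was run. Their highest mean was 1.03 CPM, so that bound was unsuited to RNAs near the floor. Of these, 4 members picked by name ran from 1.30 to 1.57. They included the highest value of the 45 and also lay near the floor, so they do not speak for the list. A change with the disease stays open and was not tested.

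Podocyte markers were lower in DKD. With the length trend removed their median was −0.28 against −0.362 (standard error over members 0.095, camera adjusted p 0.0255 at the preset correlation), which argues against length as the whole cause, though without this removal the list had adjusted p = 0.647 with an estimated correlation. A smaller share of glomeruli in the DKD libraries cannot be told apart from a change in podocytes: the podocyte median lay −0.183 from that of endothelial and mesangial markers, with a 95% bootstrap interval over members of −0.388 to 0.089 that holds 0. A loss of podocyte transcripts with the disease stays open and was not tested separately.

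Proximal tubule markers were lower in DKD, though the libraries were made from isolated glomeruli, and abundant members such as Kap and Slc34a1 stood at 12954 and 4496 CPM in Control. A smaller share of tubule in the DKD libraries cannot be told apart from regulation in tubule cells: 2 of 34 members lay above 0 by more than 2 standard errors, Pck1 (2.21 ± 0.42) and Slc13a1 (0.90 ± 0.23), too few to speak for the list. Without Control replicate 3 the median was −0.332 against −0.637 (standard error over members 0.127, camera adjusted p 0.00491). It stayed past the threshold at the preset correlation (with all 6 libraries the list had adjusted p = 0.647 with an estimated correlation), which argues against that library as the whole cause, but it exceeded 50% of the full shift by less than 1 standard error, so that library may carry a large part. A mix of both stays open too.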
